A study of Eucalyptus grandis with 3 samples.

How the data were processed

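Expression was measured in leaves of Eucalyptus grandis clone Eg9, from cuttings 40 days old, on 3 custom Agilent Eucalyptus 2-colour arrays. Per the labels' protocols, rooted cuttings stood for 3 h in Hoagland solution with PEG at -0.225 MPa or in Hoagland solution alone, total RNA was isolated from leaves, and 500 ng of each RNA was labelled. Each array carried RNA of a treated and of a control sample, and the labels call the 3 arrays biological replicates 1, 2 and 3. They do not say whether each replicate came from separate plants, so p-values measure the spread between these arrays, which may be partly technical. All 3 arrays were on 1 slide with 1 scan time, so no slide or scan batch could be tested.

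The dyes were swapped on array 2. Per the labels of each sample, treated RNA carried Cy5 (red) on arrays 1 and 3 and Cy3 (green) on array 2. The general labelling protocol gives Cy3 for control and Cy5 for test samples, and the design written before the data were examined assumed that orientation throughout, so the labels of the single samples were followed instead. Every ratio was turned to treated over control. With 2 arrays in one orientation and 1 in the other, a dye effect does not cancel fully in the mean.

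Per the file headers, the authors' images were read with Agilent Feature Extraction 11.5.1.1, which gives for each spot the mean intensity and the local background intensity in each channel. Per the file headers it also gives processed signal intensities, background-subtracted, detrended and dye-normalized by linear and lowess steps. The log10 values, ratios of red over green, were written by the same software after the dye normalization named in its settings, per the file headers, before they were deposited. The submitters' processing notes name Agilent Feature Extraction with no version. The authors' deposited value table holds log2 ratios. They equalled log2 of the ratio of the processed signals, turned to treated over control, within 0.0051 for 100% of probe values, while 85.2% lay within that tolerance of the log10 ratio column in log2. Its column medians were -0.14, -0.08 and -0.12, so the table was not centred. Why the log ratio column differs from the table for the other values is not given in the sources used here.

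Analysis started from the mean and background intensities, in R 4.3.3 with limma 3.58.1. Background was corrected with normexp (offset 50) on all spots, and ratios were normalized by loess within each array with control spots at weight 0. Of 62976 features per array, 1011 positive and 308 negative control spots were left out, as were 7, 5 and 10 gene spots flagged as non-uniform or as population outliers on arrays 1, 2 and 3. Saturated gene spots numbered 0. Median intensities of gene probes were 165.9, 268.7 and 216.6 in the treated RNA and 225.7, 188.1 and 228.0 in the control RNA. A probe was tested if it was well above background in the treated RNA on all 3 arrays or in the control RNA on all 3 arrays. The filter had been written by dye channel, which with the swap no longer follows the RNA, and the version by channel was run as an alternative.

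Each probe's mean log2 ratio was tested against 0 (two-sided) with limma's lmFit and eBayes, the array being the block of its treated and control sample, and adjusted over all tested probes by Benjamini-Hochberg at 0.05. The prior had 2.57 degrees of freedom. A gene was represented by its brightest tested probe, and the range over probes is given for a named gene where the means of its probes differed by more than 0.5. Where the control was not well above background on any array, a lower bound on the fold was computed per channel after loess and Aquantile, which is open to dye bias with unbalanced swaps.

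Gene identifiers, symbols and descriptions were those of the array files, in which symbols are those of similar genes of other plants. The reference table of RefSeq genes did not hold these genome identifiers and named none of the genes given here. Of the gene probes, 7914, for 3279 identifiers, had a description of function, and 4000 of these were tested. The array design marks 11402 gene probes as cross-hybridising. No genome build or coordinates were used.

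The 36 gene lists were fixed as patterns over the descriptions before the data were examined. They cover osmolyte, late embryogenesis and dehydrin, abscisic acid, heat shock, aquaporin, AP2/ERF, NAC, WRKY, MYB, homeodomain leucine zipper, antioxidant, glutathione S-transferase, class III peroxidase, photosystem, Calvin cycle, ribosomal, wall-loosening, lignin, flavonoid, jasmonate, ethylene, auxin, gibberellin and cytokinin, calcium, terpene, wax, histone and cyclin, pathogenesis-related (PR), senescence, starch and sucrose, and reference genes. The others are markers of guard cells, phloem, xylem, root and meristem. Lists with at least 5 tested genes were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the 26 lists. Camera compares a list with the rest of the 2100 described genes, while fry tests the list's own ratios against 0. With an estimated correlation camera takes its degrees of freedom from the 3 arrays, not from the number of genes, so a list could hardly pass. The patterns do not find every gene of a theme, such as 2 genes described as nine-cis-epoxycarotenoid dioxygenase that the abscisic acid pattern missed. Some can also take genes outside a theme. The homeodomain pattern takes any numbered homeobox protein, and the AP2/ERF pattern takes genes described as AP2/B3-like.

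Genes were named by a rule written beforehand. It takes the 10 highest and the 10 lowest described genes that passed, filled by smallest p where too few passed, and the 2 members of smallest p of each tested list. Other members of a list serve as examples, and these and the genes named in the other observations were chosen after their values were seen.

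The probe test and the list test were run on simulated data with known answers. With 200 probes changed among 42377, 117 were called, 3 of them falsely. A list of 16 genes shifted by a log2 ratio of 1 was called by camera with the preset correlation in 100% of 100 simulated sets. Of unshifted lists, 3.48% had an unadjusted p under 0.05 in that test. The simulated noise was independent between genes and lists were drawn at random, so these rates do not cover lists of correlated genes. Alternatives were other background corrections (offsets 0 and 16, and none), median centring, the scanner software's log ratio, the deposited table, other filters, flags, variance models, tests and units, separate channels and leaving out each replicate. Added after seeing the data were a dye term, array 2 not turned, the filter by dye channel, specific probes alone and, for named genes, averaged probes.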

Results

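Leaf RNA from rooted cuttings of Eucalyptus grandis, a fast-growing plantation tree, was compared after 3 h in nutrient solution with polyethylene glycol (PEG) and after the same solution without it. PEG lowers the water potential around the roots, here to -0.225 MPa, so that water is harder to take up, and the study's title gives the search for genes responsive to this water stress as its purpose. There was 1 comparison, PEG against control, measured as a ratio within each of 3 arrays, 1 for each biological replicate named in the labels. Each array held 61657 gene probes. Between 69.9% and 73.9% of them were well above background in the treated RNA, and between 67.0% and 73.4% in the control RNA. The 42388 probes that passed the signal filter represented 21142 sequences, of which 2100 were genes with a description of function. All values below are log2 ratios of PEG over control, so that positive values mean higher signal with PEG, and the number of arrays limits their precision.

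Genes for the synthesis of protective sugars were higher as a group in PEG-treated leaves when limma's camera test used its preset correlation of 0.01 (adjusted p 1.15e-05). The same list had an adjusted p = 0.984 with an estimated correlation and an adjusted p of 0.722 in fry, limma's rotation test of a list's ratios against 0. With an estimated correlation camera takes its degrees of freedom from the 3 arrays, so no list could easily pass. The osmolyte list, fixed before the data were examined, held 16 tested genes for galactinol, raffinose-family and trehalose synthesis, and their median log2 ratio was 1.11, with 10 genes above 0 on all 3 arrays and 0 below 0 on all 3. Galactinol synthases, which make the galactosyl donor for raffinose, had high values in several gene copies annotated as galactinol synthase 2. Among these, Eucgr.L00249 had 2.98 ± 1.44 (SD, n = 3), Eucgr.L03244 had 2.65 ± 1.84 and Eucgr.L00243 had 2.42 ± 1.14. Raffinose synthase genes Eucgr.I01755 and Eucgr.I01757 had 2.81 ± 0.92 and 1.72 ± 0.51, and a trehalose-6-phosphate phosphatase, ATTPPB (Eucgr.K00334), had 2.66 ± 0.76. Other members stayed near 0, such as galactinol synthase 1 (Eucgr.H00906) with 0.05 ± 0.37 and ATTPS9 (Eucgr.B03950) with 0.04 ± 0.29.

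The camera test set the osmolyte list against the other described genes, and the estimated correlation between its genes was 0.437. In fry the unadjusted p was 0.0819. No member passed over all tested probes, 9 had an unadjusted p under 0.05, all of them higher, and 7 passed when adjusted over the list alone. The list median was 0.54, 0.52 and 2.41 on arrays 1, 2 and 3. It was 0.51 without replicate 3 and lay between 0.51 and 2.01 over 16 alternative settings. The galactinol synthase 2 and raffinose synthase copies are paralogs, and 5 of the 16 genes, among them Eucgr.L00243, Eucgr.I01755 and Eucgr.I01757, were read by probes that the array design marks as cross-hybridising, so these values are not independent of each other. The 2 probes of ATTPPB (Eucgr.K00334) differed, with 0.37 and 2.66. In Eucgr.L00245, also a galactinol synthase 2, the control was not well above background on any array, so only a bound of at least 2.02-fold higher was available, and the list median was 1.07 with this gene at its bound.

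Pathogenesis-related genes, which encode secreted defence proteins, were also higher as a group with the preset correlation only (adjusted p 0.00227). Their list had an adjusted p = 0.984 with an estimated correlation and an adjusted p of 0.417 in fry. The PR list held 14 tested genes, its median log2 ratio was 0.52, and 6 genes were above 0 on all 3 arrays and 0 below 0 on all 3. The members with the smallest p were basic chitinases, enzymes that cleave fungal chitin. Eucgr.I02267 had 2.66 ± 0.61 (SD, n = 3), Eucgr.I01495 had 2.37 ± 0.54, Eucgr.I02271 had 2.13 ± 0.77 and Eucgr.I02240 had 1.09 ± 0.33. Another basic chitinase, Eucgr.J02519, had 0.38 ± 0.35. PR1 (Eucgr.G01134), a marker gene of salicylic acid responses, had 3.63 and 4.15 on arrays 1 and 2 and -0.03 on array 3.

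For the PR list the unadjusted p was 0.0573 with an estimated correlation, which was -0.029, and 0.0161 in fry. No member passed over all tested probes, 6 had an unadjusted p under 0.05, all higher, and 4 passed when adjusted over the list alone, all of them basic chitinases. These chitinases are paralogs, and Eucgr.I02240 was read by a cross-hybridising probe. The 3 probes ranged from 0.73 to 2.37 in Eucgr.I01495, from 0.98 to 2.13 in Eucgr.I02271 and from 2.09 to 2.66 in Eucgr.I02267. The PR call was lost when probes had to be well above background in both RNAs on every array (median 0.37, adjusted p 0.0522), and over 16 alternative settings the median lay between 0.20 without a signal filter (adjusted p 0.0451) and 0.87 with the software's log ratio (adjusted p 0.000255). Both list calls were lost when the ratio of array 2 was left in its dye direction, against the labels, with adjusted p 0.484 for each.

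**Figure D1:**
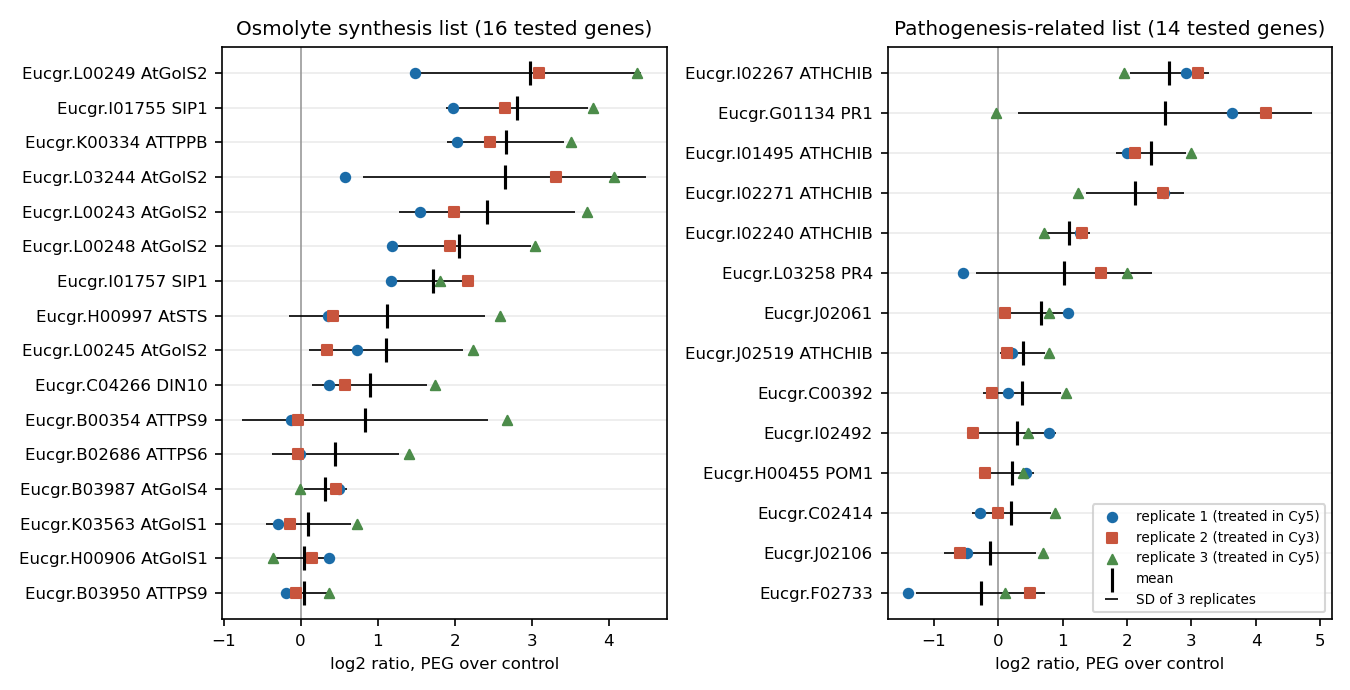
Log2 ratio of PEG over control (horizontal axis) for each tested gene of the osmolyte list (left) and the PR list (right). Coloured symbols are the 3 arrays, black ticks the means and horizontal lines the SD of the 3 replicates. In the left panel 10 of 16 genes lie above 0 on all 3 arrays, and PR1 in the right panel lies near 0 on array 3 and above 3 on the others.

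No single probe passed the test across the array. In limma with Benjamini-Hochberg adjustment 0 probes had an adjusted p under 0.05, the lowest adjusted p was 0.125, and a plain one-sample test per probe also gave 0. At an unadjusted p under 0.05 there were 3725 probes, against 2119.4 expected by chance, of which 2967 (79.7%) were higher and 758 lower. In the plain test per probe the split at that threshold was 1503 higher and 1275 lower. With the scanner software's own log ratios the higher share was 58.7%, with 2338 higher and 1647 lower. With the authors' deposited value table it was 58.6%. More than 2-fold higher on every array were 237 probes of 149 sequences, among them 27 described genes, and more than 2-fold lower were 10 probes of 5 sequences. Over 2 arrays at a time these counts were 832 higher and 53 lower without replicate 1, 520 and 61 without replicate 2, and 413 and 40 without replicate 3.

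Among described genes, those with the smallest p in each direction were taken, since none passed. The 10 higher ones had log2 ratios of 1.01 to 2.73, were above 0 on all 3 arrays and had adjusted p between 0.201 and 0.300. ATNFXL2 (Eucgr.E03865), a zinc finger transcription factor, had 2.16 ± 0.31 (SD, n = 3), and osmotin 34 (Eucgr.D01888), a thaumatin-like protein first known from salt-adapted cells, had 1.44 ± 0.24. Germin 3 (Eucgr.C03488) had 1.87 ± 0.41, the F-box gene EDL3 (Eucgr.H01519), read by a cross-hybridising probe, had 2.73 ± 0.74, and a GDSL-like lipase (Eucgr.D00574) had 1.42 ± 0.07. The transporter PDR4 (Eucgr.C04145) had 1.01 ± 0.06, with its 3 probes ranging from 0.23 to 1.01, and a small nuclear ribonucleoprotein gene (Eucgr.B03843) had 1.27 ± 0.29. The remaining 3 were the chitinases Eucgr.I02267 and Eucgr.I01495 and the trehalose-6-phosphate phosphatase gene described above.

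The 10 lower genes had log2 ratios of -1.99 to -0.66, were below 0 on all 3 arrays and had adjusted p between 0.310 and 0.404. The lowest mean was that of Eucgr.K00128, annotated as an integrase-type DNA-binding protein, at -1.99 ± 0.64 (SD, n = 3). MYB55 (Eucgr.D02099) had -1.32 ± 0.64 (probes from -1.32 to -0.82), an F-box gene (Eucgr.A01226) had -1.17 ± 0.35 and a 2-hydroxyacid dehydrogenase gene (Eucgr.E01337) had -1.13 ± 0.38. The sugar and polyol transporter ATPLT5 (Eucgr.G00453) had -1.07 ± 0.37, ANAC039 (Eucgr.C02105) had -0.97 ± 0.33 and TBL45 (Eucgr.J01893) had -0.90 ± 0.31 (probes from -0.90 to -0.33). The phosphate transporter PHT1;7 (Eucgr.H00164) had -0.72 ± 0.21, a dehydroquinate dehydratase gene of the shikimate pathway (Eucgr.H04428) -0.74 ± 0.18, and a nucleoside triphosphate hydrolase gene (Eucgr.K00303) -0.66 ± 0.08. The 67 genes named by the rule kept their sign in 1249 of 1255 values computed under other settings. The 6 turned values all came from leaving array 2 in its dye direction. These genes were chosen on the same arrays. Where all 3 arrays share a sign, leaving out a replicate cannot turn it, so the count says little about reproducibility.

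**Figure D2:**
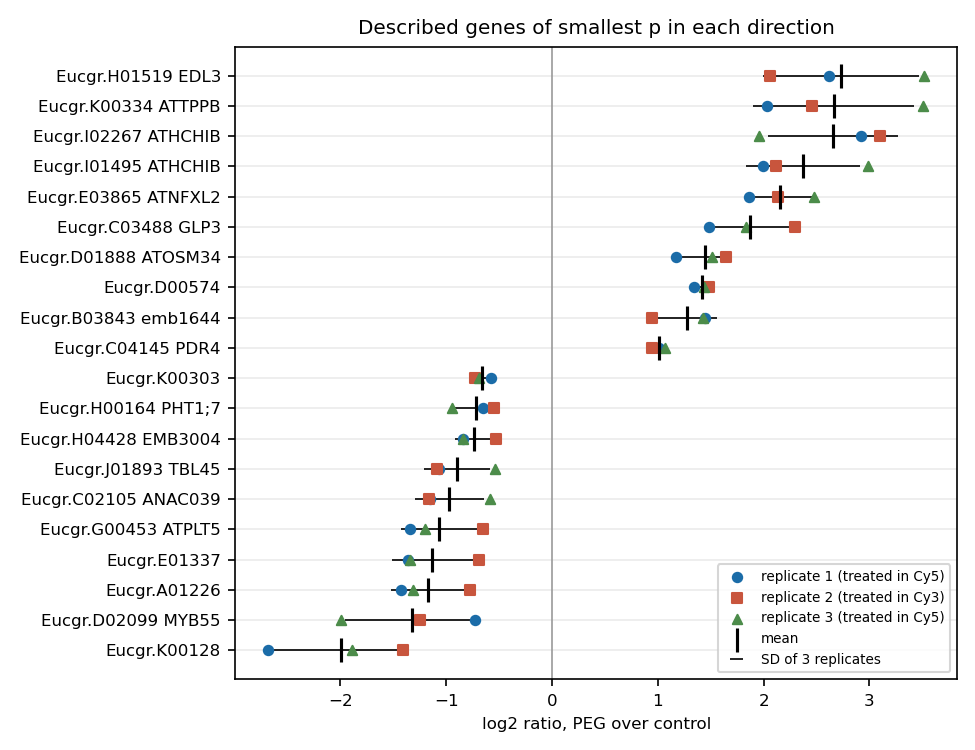
Log2 ratio of PEG over control (horizontal axis) of the 10 described genes with the smallest p in each direction. Coloured symbols are the 3 arrays, black ticks the means and horizontal lines the SD of the 3 replicates. Each gene lies on 1 side of 0 on all 3 arrays, and 0 of these 20 genes passed the adjusted test.

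Of the 26 lists with at least 5 tested genes, only these 2 passed the camera test with its preset correlation of 0.01, and 0 passed with an estimated correlation or in fry. Since the degrees of freedom with an estimated correlation came from the 3 arrays, a list could hardly pass there. Adjusted p of lists below are from the preset test. Adjustment of genes over a list alone, here and above, does not correct for the 26 lists, so some such passes can arise by chance. Genes for late embryogenesis abundant proteins and dehydrins, which protect cells that dry out, had a median of 0.89 over 5 genes (adjusted p 0.0929), with LEA14 (Eucgr.D02327), read by a cross-hybridising probe, at 0.84 ± 0.32 (SD, n = 3) passing when adjusted over the list alone. Aquaporins, the water channels of cell membranes, had a median of 0.83 over 6 genes (adjusted p 0.291), and the tonoplast aquaporin GAMMA-TIP3 (Eucgr.J02074) had 0.03, 2.74 and 2.64 on the 3 arrays, with probes from 0.79 to 1.81. Wall-loosening genes had a median of 0.43 over 17 genes, of which 8 were above 0 on all 3 arrays and 0 below 0 on all 3 (adjusted p 0.0929). Expansin genes ATEXPA1 (Eucgr.G02490) and ATEXPA13 (Eucgr.C02271) had 1.44 ± 0.70 and 0.66 ± 0.27 there, both read by cross-hybridising probes. Auxin genes had a median of -0.17 over 22 genes (adjusted p 0.0562), although the member with the smallest p, Eucgr.A01061, a cross-hybridising probe, had 2.06 ± 1.93. Without replicate 1 the late embryogenesis (adjusted p 0.0468), aquaporin (0.0222) and lignin (0.00702, lower) lists passed as well. Their medians without replicate 3 were 0.44 (adjusted p 0.159), 0.29 (0.521) and 0.19 (0.541). The auxin list passed in 6 settings, with adjusted p of 0.0154 to 0.0473. Without replicate 1 the auxin median was 0.008 (adjusted p 0.357), and over all alternative settings it lay between -0.44 and 0.07. The same ranges were 0.14 (without a signal filter) to 1.56 (offset 0) for late embryogenesis, 0.12 to 1.07 for aquaporin and 0.10 to 0.61 for wall-loosening genes, whose median was 0.23 without replicate 3 (adjusted p 0.331).

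Transcription factor lists held members of both signs. The AP2/ERF and DREB list had a median of 0.20 over 12 genes (adjusted p 0.854), while CBF4 (Eucgr.A02818), a C-repeat-binding factor of the DREB family, had 2.64 ± 1.36 (SD, n = 3). The list's pattern also took genes described as AP2/B3-like, NGA1 (Eucgr.E01093, -0.34) and VRN1 (Eucgr.G01241, 0.27). It did not take Eucgr.K00128, described as an integrase-type DNA-binding protein, so the list may lack members of the family. The NAC list had a median of 0.13 over 12 genes (adjusted p 0.577), and ANAC039 passed as lower when adjusted over the list alone. The MYB list had 0.05 over 30 genes (adjusted p 0.701), with AtMYB103 (Eucgr.C02390), a cross-hybridising probe, at 0.91 ± 0.21 and MYB55 (Eucgr.D02099) lower as given above, while a second gene annotated MYB55 (Eucgr.F03175) had 0.58 ± 0.33 and was above 0 on all 3 arrays. The homeodomain leucine zipper list had -0.11 over 6 genes (adjusted p 0.670). Its pattern takes any numbered homeobox protein, such as AtHB31 (Eucgr.G00066) and AtHB33 (Eucgr.F01575), so not every member need be of that family. Of hormone lists, gibberellin and cytokinin genes had -0.30 over 5 genes (adjusted p 0.291), ethylene genes 0.15 over 5 (0.820) and jasmonate genes 0.05 over 9 (0.983). In the jasmonate list, LOX5 (Eucgr.H03535), read by a cross-hybridising probe, had 0.84 ± 0.30 and passed as higher when adjusted over the list alone, while JAZ3 (Eucgr.G02116) had -0.69 ± 0.48. Calcium signalling genes had 0.06 over 20 (0.971). Medians depended on the settings, with ranges over the alternatives of -0.02 to 0.48 (AP2/ERF), -0.22 to 0.29 (NAC), -0.01 to 0.16 (MYB), -0.40 to 0.05 (homeodomain), -0.62 to 0.07 (gibberellin and cytokinin), 0.08 to 0.30 (ethylene), -0.04 to 0.23 (jasmonate) and -0.03 to 0.12 (calcium).

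Metabolic and structural lists had medians of either sign. Starch and sucrose genes had 0.34 over 14 genes (adjusted p 0.803), in which the beta-amylase BAM1 (Eucgr.H02879) had 0.83 ± 0.71 (SD, n = 3). Photosystem genes had 0.28 over 14 (0.701), flavonoid genes 0.27 over 7 (0.701), and the flavonoid list held 1 gene, Eucgr.F01378, at 0.64 ± 0.14 (probes 0.30 and 0.64), that passed as higher over the list alone. Lignin genes had -0.0025 over 16 (0.220), terpene genes 0.69 over 7 (0.983), class III peroxidases 0.76 over 5 (0.670) and glutathione S-transferases 0.10 over 7 (0.854). Heat shock protein genes had 0.12 over 22 (0.983), senescence genes 0.31 over 7 (0.701), and histone and cyclin genes 0.15 over 9 (0.978). In that last list the cyclin CYCD3;2 (Eucgr.G01371) passed as higher over the list alone with 0.78 ± 0.26, and the cyclin-dependent kinase inhibitor ICK1 (Eucgr.H02008) as lower with -0.53 ± 0.06. Genes often used as references had a median of 0.005 over 11 (0.767), and markers of xylem, a tissue that leaf samples also contain, 0.34 over 5 (0.983). Ranges of the medians over the alternatives were 0.005 to 0.40 (starch and sucrose), 0.04 to 0.44 (photosystem), -0.04 to 0.54 (flavonoid), -0.23 to 0.19 (lignin), -0.34 to 1.01 (terpene), -0.20 to 1.496 (peroxidase) and -0.06 to 0.23 (glutathione S-transferase). They were 0.04 to 0.22 (heat shock), -0.08 to 0.67 (senescence), 0.04 to 0.25 (histone and cyclin), -0.08 to 0.15 (reference) and -0.02 to 0.82 (xylem). The camera direction was lower while the median and mean were above 0 in the NAC, MYB, reference, calcium and jasmonate lists. The camera test compares a list with the other described genes, and described probes as a whole had a median of 0.24 on array 3 and of -0.01 and -0.004 on arrays 1 and 2.

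A further 10 lists had fewer than 5 tested genes and were not tested as groups. The 4 abscisic acid genes had values of 0.39 to 1.54, the highest in HAB1 (Eucgr.C03732), which had 1.54 ± 1.86 (SD, n = 3), with probes from 0.92 to 1.54. The 4 WRKY genes lay between -0.42 and 0.48, the 3 antioxidant genes between -0.84 and 1.17, the 4 Rubisco and Calvin cycle genes between -0.04 and 0.80, and the 4 wax genes between 0.10 and 0.68. The 1 ribosomal gene had 0.84 ± 1.65, with probes from 0.002 to 0.84. Markers of other tissues had 2 phloem genes (-0.14 and 0.18), 2 root genes (-0.32 and 0.05), 1 meristem gene (-0.16) and 0 guard cell genes. None of these genes passed the test over all probes.

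**Figure D3:**
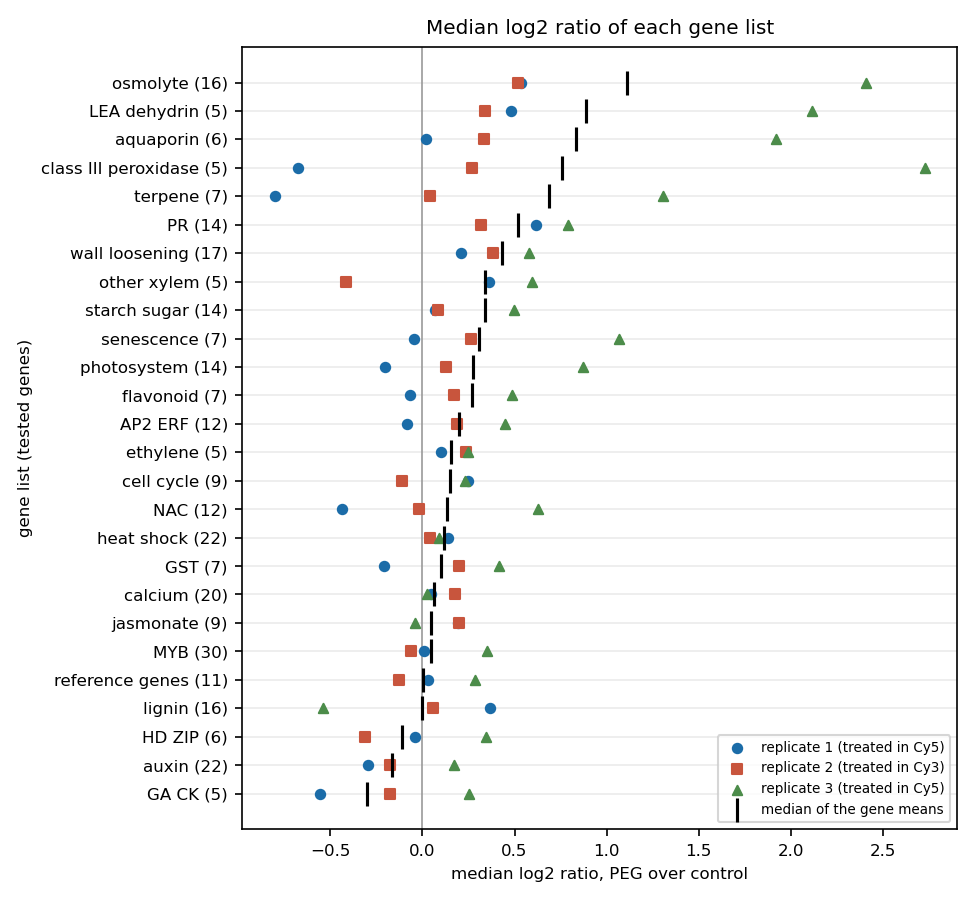
Median log2 ratio of PEG over control (horizontal axis) of each gene list with at least 5 tested genes, ordered by the median of the gene means (black ticks). Coloured symbols are the list medians on the 3 arrays, and tested genes per list are in parentheses. The osmolyte list has the highest median, 1.11, and in array 3 most lists lie to the right of their other values.

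The 3 arrays differed from each other more for strongly shifted probes than for the rest. Across the 42388 tested probes, which are not independent replicates, the correlation of log2 ratios was 0.231 between arrays 1 and 2, 0.195 between arrays 1 and 3 and 0.318 between arrays 2 and 3. The median SD over arrays was 0.27 for all tested probes and 1.47 for the 38 probes that were over 4-fold higher on every array, whose median log2 ratio was 4.02. In simulated data with 42377 probes and this comparison's variance prior, the same test recovered 0 of 50 probes shifted by a log2 ratio of 1. It recovered 26 of 50 shifted by 2, 43 of 50 shifted by 3 and 45 of 50 shifted by 4. The simulated noise did not depend on the size of the shift, unlike the spread of the real probes given above. None of those 38 probes passed, so the simulated recovery does not carry over to them.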

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

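The tests of osmolyte genes against dye and brightness, of strongly higher transcripts and of described genes on array 3, and the count of sign patterns, were chosen only after the results were seen. The test with specific probes was chosen before its result was seen.

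Data outside the comparison also held signal. The 350 spots for spike-in RNA were well above background in both channels for 100%, 100% and 99.71% of spots on arrays 1, 2 and 3, while 3.25%, 0.65% and 2.92% of the 308 negative control spots were above it in either channel. The scanner software's slope of observed on expected log ratios of the spike-ins was 0.854, 0.753 and 0.749 on the 3 arrays, with correlations of 0.975, 0.956 and 0.958. On these spots a slope under 1 means that ratios were measured smaller than the expected ones.

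The 3725 probes at an unadjusted p under 0.05 were compared with the counts after turning the sign of 1 array. Of the 4 sign patterns, 1 reached that count, the real one, and the highest of the others gave 1666. So few patterns are too few for a share under 0.05.

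The osmolyte list was higher with PEG in the camera test with its preset correlation, with an adjusted p = 0.984 with an estimated correlation and 0.722 in fry. The estimated setting could hardly call any list. Averaging both dye orientations equally, so that a dye effect cancels, left a list median of 0.93, with 16 of 16 genes above 0. The upper limit was 0.37 for 95% of 10000 brightness-matched lists of described genes. On array 2 alone the median was 0.52 (upper limit 0.34), with 12 of 16 genes above 0. This argues against dye bias as the whole cause. Matched lists were drawn gene by gene at random, while the estimated correlation in the osmolyte list was 0.437, so their limits may be too narrow. With the 11 genes read by specific probes the median was 0.84 (upper limit 0.44), which argues against cross-hybridisation, and the median over the 3 arrays was above 100% of matched lists, which argues against a brightness trend. A response of these genes to PEG remains a hypothesis, and what made array 3 higher than the others for this list stays open.

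The strongest transcripts were mostly contigs without a description. Of 63 probes over 4-fold higher on arrays 1 and 3, all 63 were above 0 on array 2, where the dyes were swapped, with a median of 2.29 (quartiles 1.60 and 3.82), which argues against dye bias. When sequences were chosen by their brightest probe on arrays 1 and 3 instead, 17 of 38 had other tested probes. These 30 probes had a median of 1.67 on array 2 (quartiles 0.92 and 3.58), with all 30 above 0. The lower quartile had to exceed 1 to argue against single faulty probes, so this test did not decide. Of the 25 sequences with a probe over 4-fold higher on every array, 11 had more than 1 tested probe, and in 7 of these all tested probes were over 4-fold higher. A single faulty probe cannot explain those 7, nor contig_83728, whose 3 probes had means of 3.11 to 3.42. It stays open for the 14 sequences with 1 tested probe and for Eucgr.I02327 (0.30 to 4.06), Eucgr.K00334 (0.37 to 2.66) and Eucgr.K02328 (1.35 to 3.48), whose probes differed.

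Described genes were higher on array 3 than probes without a description. Within 20 bins of brightness the median difference was on average 0.271 on array 3 (0.126 to 0.415 over the bins), which argues against a brightness trend. The same difference was -0.021 on array 1, which had the same dye orientation, and -0.024 on array 2, which argues against a dye effect on these probes. On array 3 the 269 probes with a genome identifier but no description had a median of -0.14, against 0.24 for described probes. A difference of the third replicate's plants or RNA stays open and was not tested.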

How the results depend on the processing

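In all 22 alternatives to the probe test, 0 probes passed, with the lowest adjusted p between 0.0722 and 0.928. Treating the channels as unpaired, with no replicate block, gave 0 probes, a lowest adjusted p of 0.0749 and 3572 probes at an unadjusted p under 0.05. That count fell outside 1.5 times the 3725 reported when array 2 was not turned (1666). With probes of a gene averaged it was 1850 of 21141 tested sequences, a share of 8.75% against 8.79% of 42388 probes. It was 2494 with a dye term and 2778 with the plain test per probe, and 3583, 3091 and 3143 without replicates 1, 2 and 3. Probes over 2-fold higher on every array numbered 386 with offset 0, 422 with the software's log ratio, 418 with the deposited table and 1 with array 2 not turned, against 237, and those lower 20, 51, 49 and 7, against 10. The median of all tested probes was -0.081 with the software's log ratio, against 0.012.

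Against 2 lists called, 1 was called with both RNAs above background, 0 with array 2 not turned and 0 with an estimated correlation. Leaving out 1 replicate gave between 2 and 5 lists, 5 of them without replicate 1, and osmolyte medians of 0.508 to 1.48 and PR medians of 0.367 to 0.680. The osmolyte list kept its call in 14 of 16 settings and lost it with array 2 not turned (median 0.635) and with an estimated correlation (1.11). The PR list kept its call in 13 of 16, and lost it with both RNAs above background (0.371), with array 2 not turned (0.315) and with an estimated correlation (0.522). The estimated correlation was 0.437 for the osmolyte list but -0.029 for the PR list, which lost its call under the same switch. In camera the unadjusted p of the PR list rose from 0.000175 to 0.0573. A positive correlation between genes therefore does not explain the lost PR call. The switch also takes camera's degrees of freedom from the 3 arrays, not from the number of genes. That change raised the PR p, since a correlation below the preset one does not. For the osmolyte list the higher correlation and the fewer degrees of freedom both raise p, and their shares were not separated. Every tested list had an adjusted p of 0.984 with an estimated correlation, so that value does not tell lists apart. For the other lost calls the cause was not tested.

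Of 375 values of the other tested lists, 332 kept direction and side, 9 passed and 34 turned the direction of the camera test, none of these 34 past the threshold. The medians below are those where the camera direction turned, whether or not the median changed sign. For terpene genes they were 0.19 (offset 0), 0.702 (no background correction), 0.684 (offset 16), -0.134 (software log ratio), -0.133 (deposited table), 0.102 (no filter) and 0.531 (probes averaged). For calcium genes they were 0.0424 (offset 0), -0.0348 (software log ratio) and -0.0333 (deposited table), and for jasmonate genes 0.00212 (no filter), 0.0481 (both RNAs above background) and 0.114 (probes averaged). Heat shock genes had 0.12 with both RNAs above background and 0.0998 with specific probes. With array 2 not turned they were 0.149 (aquaporin), -0.0239 (AP2/ERF), 0.0451 (homeodomain), -0.0203 (glutathione transferase), 0.079 (ethylene) and 0.135 (reference). Leaving out 1 replicate turned the direction at least once in lists whose medians then ranged from 0.0627 to 0.216 (heat shock), 0.0704 to 0.475 (AP2/ERF), -0.0564 to 0.228 (glutathione transferase), 0.0434 to 0.445 (photosystem), -0.231 to 0.186 (lignin), 0.00251 to 0.226 (jasmonate) and 0.0585 to 0.119 (calcium). The ranges were -0.345 to 1.01 (terpene), 0.0411 to 0.229 (histone and cyclin), -0.0760 to 0.666 (senescence), -0.0475 to 0.150 (reference) and -0.0221 to 0.818 (xylem), and class III peroxidases had -0.204 without replicate 3. The cause was not tested.

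Of 1255 values of named genes, 0 passed the threshold and 6 turned sign, all with array 2 not turned: Eucgr.A00299 (-0.038), Eucgr.A01790 (0.13), Eucgr.B02780 (-0.02), Eucgr.G01970 (-0.076), Eucgr.G03138 (-0.011) and Eucgr.J02074 (-0.024). Signal over background limits the 14 described genes whose control was not well above background on any array to a bound.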

Other observations

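The genes in this part were chosen after their values were seen, none passed the test over all probes, and SDs are over 3 arrays. Among genes annotated as protein phosphatases 2C or their homologs, AHG1 (Eucgr.A02858) had 3.13 ± 1.69 and was above 2 on every array, ABI2 (Eucgr.J02003) had 1.63 ± 1.20, ATPP2CA (Eucgr.A01486) had 2.01 ± 2.64 with -0.21 on array 2, and HAB1 (Eucgr.C03732) had -0.05 on that array. A second gene annotated HAB1 (Eucgr.C03407) had -0.06, 0.78 and 1.85 on the 3 arrays, with probes from 0.414 to 0.955. These phosphatases were not tested as a group. NCED3 (Eucgr.D00291), annotated as the dioxygenase that makes the precursor of abscisic acid, had -0.66 ± 0.20 and was below 0 on all 3 arrays, and a second gene of that annotation (Eucgr.F01409) had 0.05 ± 0.71. AT-HSFB2B (Eucgr.A02804) had 0.97 ± 0.55 and MBF1C (Eucgr.C01056) 0.80 ± 0.31, both with their lowest value on array 2.

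Several sequences moved on 2 arrays and not on the other. Of 832 probes over 2-fold higher on arrays 2 and 3, 334 (40.1%) lay within 0.5 of 0 on array 1, against 153 of 520 near 0 on array 2 and 85 of 413 near 0 on array 3. Near 0 on array 1 and high on the others was NHL3 (Eucgr.K02612), with 0.46 and 2.44 on arrays 1 and 2 and a mean of 2.30 ± 1.78. A dehydrin (Eucgr.I02395), read by a cross-hybridising probe, had -0.48, 2.33 and 2.62. The opposite pattern, high on arrays 1 and 2, was seen in an alpha carbonic anhydrase (Eucgr.A01642) with 3.09, 1.43 and -0.34, and in a basic secretory protein gene (Eucgr.G01327) with 0.98, 2.82 and 0.11. The nitrate reductase NIA1 (Eucgr.F03744) had -1.24, -1.21 and 0.07. No test of a difference between replicates was run.

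Over 4-fold higher on every array were probes of 25 sequences, 17 of them contigs, 2 other expressed sequences and 6 described genes. Contig contig_19770 had the same size in its 3 probes (5.38 to 5.60). High ratios were also measured by probes of contigs that the array design pairs with defence genes, such as contig_91998 with chitinases (4.10), contig_67622 with a PR4 gene (4.48) and contig_92373 with an osmotin 34 gene (4.22).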
